A study of Homo sapiens with 12 samples.

How the data were processed

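Gene expression was measured on 12 single-colour 3' expression arrays, 1 for each of 3 epithelial populations sorted from benign prostate tissue of 4 donors. Per the labels' protocols, CD45-negative, EpCAM-positive cells were sorted by CD49f into basal and luminal cells and the luminal cells by CD38. RNA was isolated with a micro-scale column kit and amplified with a kit for picogram inputs, per the labels' protocols. The deposited values were linear intensity signals per probe set made with MAS5 in Affymetrix Expression Console, per the submitters' processing notes, and their versions are not given in the sources used here. The trimmed mean of the deposited signals, leaving out 2% at each end, was 500 on every array to 3 digits, so the deposited values were already scaled between arrays. No genome build, scan date or batch is given in the sources used here, so no coordinates are printed and no batch was tested.

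The table held 54675 probe sets, of which 62 controls were left out. Through the platform's annotation 41091 probe sets had 1 gene symbol, 1801 had several and 11721 were not named here. Symbols were updated through gene identifiers with a reference gene table of assembly GRCh38.p14, which matched 41037 probe sets. The 77 probe sets of Y-linked genes and XIST were removed before all steps. Values were taken as log2(signal + 16), which understates the change of dim genes. A probe set was kept if it lay above its array's median, the 50th percentile, on at least 4 of the 12 arrays, which left 29850, and a gene was read from its kept probe set with the highest mean, giving 12097 genes. Of these, 6538 had more than 1 kept probe set, and among the called genes with several, 0 of 814, 0 of 818 and 16 of 2034 had another probe set called in the opposite direction in the 3 comparisons (CD38-low with CD38-positive luminal, CD38-low luminal with basal, and CD38-positive luminal with basal).

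Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit on all 12 arrays with group means, contrasts, eBayes with an intensity trend), and p was adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The 21 gene lists and 9 lists of cell type markers were fixed before the data were examined and tested with limma's camera with a preset correlation of 0.01, with an estimated correlation as an alternative. The genes named for each comparison were those with the 8 largest rises and 8 largest falls among genes with adjusted p under 0.05 and the same sign in all 4 donors, up to 4 members of each list (the largest rises and falls that passed, or those with the smallest p where none passed) and the sort markers. Y-linked genes, XIST, polymorphic HLA genes, immunoglobulin and T cell receptor segments, genes with common deletions and placeholder symbols were left out by that rule. List members whose call was lost when a single array was left out were not named, except where a value without that array stands beside them, and that restriction was chosen after the values were seen. The position of the CD38-low gate was the mean of CD38-low minus basal over the mean of CD38-positive minus basal, in each donor, over genes picked by limma in the 3 other donors at adjusted p under 0.05 and at least 2-fold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

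The replicate numbers in the labels mark the donor. Deviations from the group means correlated between arrays of the same donor with a median r of 0.234 (0.129 to 0.326, over 0.1 in 12 of 12 pairs) and with a median of -0.0656 between different donors, across genes, so the arrays were treated as paired in the fit with the donor as a block. That fit is an alternative. The main fit had no donor term, and its differences, SE, list tests and counts are given unless the block is named. No arrays held identical values (0 pairs), and the highest correlation between arrays was 0.967. The fit was tested on simulated data with 200 changed genes among 12097. At log2 sizes of 1, 2 and 3 it recovered 41.8%, 88.1% and 97.0% for CD38-low against CD38-positive luminal cells, 40.3%, 91.0% and 92.4% for CD38-low luminal against basal cells and 43.3%, 85.1% and 98.5% for CD38-positive luminal against basal cells. It called 2, 6 and 10 unchanged genes in these comparisons and gave 0 wrong signs. A position placed at 0.4 was returned as 0.395 ± 0.0254 and 0.400 ± 0.0146 (SD). The simulated noise was independent between genes and arrays, with no donor effect, and far fewer genes changed than were called in the data. These values thus check the fit in a simpler setting and are not error rates for these arrays. The number of arrays limits the precision.

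Alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter and a filter at the 75th percentile, the mean of probe sets, leaving out probe sets shared between transcripts, the donor as a fixed or random block, only the 8 arrays compared, no intensity trend, array weights, a minimum fold of 2 and leaving out each array in turn. After the data were seen, 3 more were added, which left out the 2 CD38-low arrays with the most fibroblast signal, left out basal replicate 4 with CD38-low replicate 2, or took the fibroblast marker mean as a covariate. That covariate was also fitted with the donor as a block for the lists and genes where it is given. Donors' personal details were left out.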

Results

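Expression was measured in epithelial cells of benign human prostate tissue that had been sorted into 3 populations from each of 4 donors, giving 12 arrays, 4 per population. CD45-negative, EpCAM-positive cells were gated as basal (high CD49f) or luminal (low CD49f), and the luminal cells were divided into a CD38-low gate, labelled as enriched for luminal progenitors, and a CD38-positive gate, called mature luminal cells. The values were deposited array signals, scaled to a common trimmed mean of 500 or close to it on every array. The median signal lay between 86.8 and 133 on 11 arrays and was 168 on basal replicate 4. The number of arrays limits the precision. Differences below are on the log2(signal + 16) scale and are given ± SE with n = 4 arrays per group, and a gene said to have risen or fallen passed limma's test over all genes and moved the same way in all 4 donors unless stated otherwise. Counts adjusted over a list alone rest on the threshold only.

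The 3 populations formed separate groups in the principal components of all genes tested. PC1 held 44.9% of the variance and ordered the groups from basal (scores from -53.5 to -49.8) through the CD38-low gate (-20.5 to 2.95) to CD38-positive luminal cells (57.4 to 62.6). PC2 held 14.8%, and on it basal replicate 4 lay at -72.0, while the other basal arrays lay between -3.91 and 12.2. The mRNA of the sort markers followed the gates in part. CD38 had a mean log2 signal of 10.2 ± 0.234 (SD, n = 4) in CD38-positive, 6.79 ± 0.482 in CD38-low and 5.52 ± 0.676 in basal cells. ITGA6, which encodes CD49f, stood at 13.7 ± 0.138 in basal cells against 11.9 ± 0.296 and 11.6 ± 0.424 in the CD38-low and CD38-positive gates. EPCAM lay between 13.0 and 13.2 in all 3 group means, and PTPRC, which encodes CD45, did not pass the filter on dim signals in any comparison, with group means from 4.69 to 4.95. The log2 ratio of 3' to 5' control signals, a sign of RNA quality, differed by -0.0872 between CD38-low and CD38-positive luminal cells, by -0.102 between CD38-low and basal cells and by -0.0149 between CD38-positive and basal cells (exact two-sided permutation tests with 70 assignments, p = 0.114, 0.143 and 0.829, Benjamini-Hochberg adjusted over these 3 p = 0.214, 0.214 and 0.829). Against basal cells both controls went opposite ways. For CD38-low minus basal cells the difference was 0.133 on ACTB (exact permutation p = 0.257) and -0.338 on GAPDH (exact permutation p = 0.0286, not adjusted, the smallest that 70 assignments allow). For CD38-positive minus basal cells it was 0.155 on ACTB (exact permutation p = 0.0857) and -0.185 on GAPDH (exact permutation p = 0.429). These tests ignore the donors. In each donor the CD38-low ratio was below the basal one on the mean of both controls and on GAPDH. On ACTB it was above the basal one in every donor but that of replicate 2.

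**Figure D1:**
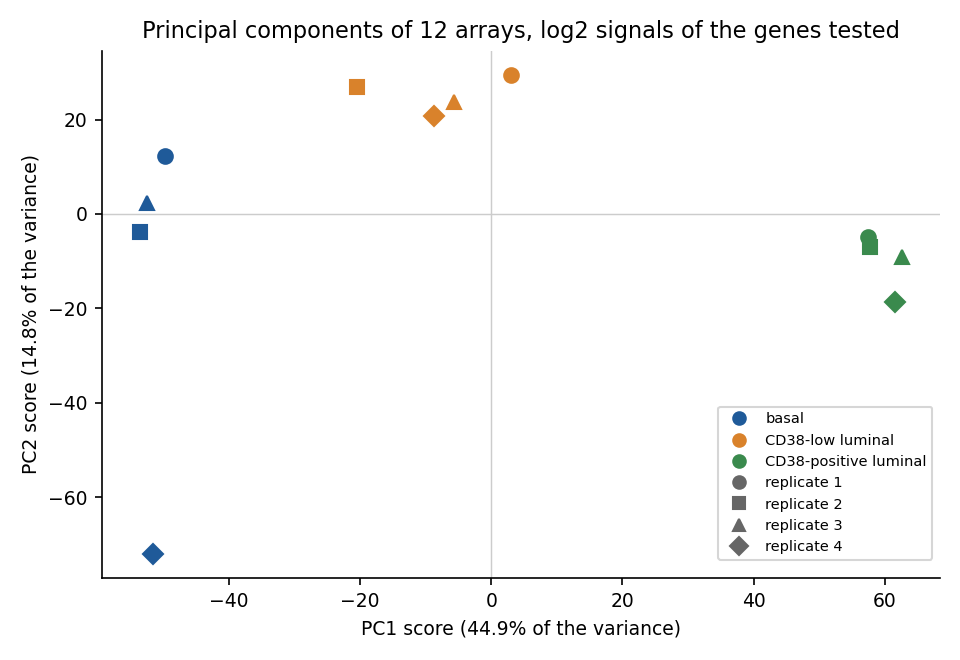
Scores of the 12 arrays on the first and second principal components of the log2 signals, with colour for the sorted population and symbol for the replicate number, which marks the donor. The CD38-low arrays lie between the other populations on PC1 (-20.5 to 2.95), and basal replicate 4 lies apart on PC2 (-72.0).

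The comparison of CD38-low with CD38-positive luminal cells asks how the progenitor-enriched gate differs from the gate labelled mature luminal. CD38-low cells had much higher signals of secreted proteins known from club cells and mucosal epithelia. SCGB1A1, a secretoglobin of airway club cells, rose by 6.47 ± 0.46, OLFM4, a secreted glycoprotein of intestinal crypts, by 5.19 ± 0.52, and BPIFB1, a secreted airway protein, by 4.90 ± 0.89. KRT13, a keratin of stratified epithelia that do not cornify, rose by 4.68 ± 0.50, and the cornified envelope proteins SPRR3 and SPRR1B rose by 4.75 ± 0.93 and 4.67 ± 0.88. KRT13 had a higher mean log2 signal in basal cells, 13.0 ± 0.352 (SD, n = 4) against 11.2 ± 1.26 in CD38-low cells. With the fibroblast marker mean as a covariate, SPRR3 and SPRR1B stood at -0.36 ± 1.10 and -0.94 ± 1.05 against basal cells (limma adjusted p = 0.877 and 0.632). SCGB1A1 was high in basal cells too, from 11.3 to 11.9 over their arrays, and CD38-low cells lay 1.67 above them (limma adjusted p = 0.0311). The rises of KRT13, SPRR3 and SPRR1B, and much of that of SCGB1A1, thus go with the basal signal as well. The ubiquitin ligase TRIM31 (5.01 ± 0.43) and the galactosyltransferase B3GALT5 (4.76 ± 0.69) completed the 8 largest rises. The largest falls were those of CD177, a surface glycoprotein best known from neutrophils (-5.08 ± 0.31), the neuropeptide NPY (-4.51 ± 0.31), the cell surface dipeptidyl peptidase DPP4 (-4.46 ± 0.50) and the lipoxygenase ALOX15B (-4.27 ± 0.45). CPLX3 (-4.13 ± 0.56), CWH43 (-4.05 ± 0.50), the long noncoding RNA DRAIC (-4.05 ± 0.48) and the adhesion protein CNTNAP2 (-3.90 ± 0.58) followed. Adjusted p-values of these 16 genes ranged from 1.33e-06 to 0.00356. CD38 itself fell by 3.43 ± 0.34 (limma adjusted p = 2.62e-05), while EPCAM (-0.03 ± 0.16) and ITGA6 (0.37 ± 0.21) did not pass.

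Among the fixed lists, secretory luminal genes fell together in CD38-low cells. Of 23 tested members 13 fell, none rose and 10 did not pass (16 fell adjusted over the list alone; camera adjusted p = 6.74e-15, 0.0201 with an estimated correlation), NPY and DPP4 leading. Androgen-responsive genes had 13 falls, 1 rise and 15 members that did not pass out of 29 (15 falls and 1 rise adjusted over the list alone; camera adjusted p = 3.59e-06, 0.0315 with an estimated correlation). The kallikrein KLK2 fell by 2.55 ± 0.41 and the transcription factor MAF fell by 2.34 ± 0.24, while HPGD, which breaks down prostaglandins, rose by 2.52 ± 0.38. Club and hillock genes had 16 rises and no fall out of 28 (17 rises adjusted over the list alone; camera adjusted p = 6.65e-12, 0.0315 with an estimated correlation). Of 22 basal genes 8 rose, 1 fell and 13 did not pass (10 rises and 1 fall adjusted over the list alone; camera adjusted p = 9.87e-05, 0.0218 with an estimated correlation). Caveolin CAV1 rose by 4.11 ± 0.39 and the basal keratin KRT5 by 3.66 ± 0.28, while the membrane peptidase MME fell by 2.74 ± 0.28.

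Progenitor-associated genes had 5 rises, no fall and 10 members that did not pass out of 15 (7 rises adjusted over the list alone; camera adjusted p = 0.000632, 0.0218 with an estimated correlation). The survival factor BCL2 rose by 2.71 ± 0.27 and PROM1, the CD133 antigen, by 2.63 ± 0.40. In the Wnt list 8 of 17 genes rose and none fell, also adjusted over the list alone (camera adjusted p = 3.23e-05, 0.0201 with an estimated correlation). The secreted protein DKK3 rose by 2.92 ± 0.33 and the Wnt receptor FZD10 by 2.78 ± 0.56. DKK3 was higher still in basal cells on average. BCL2 ranged from 9.68 to 10.7 over the basal arrays, against means of 10.7 in CD38-low and 8.02 in CD38-positive cells. The rises of DKK3 and BCL2 thus go with the basal signal as well. Neither the progenitor nor the Wnt list passed between CD38-low and basal cells, as given below. In the polyamine, citrate and zinc list 8 of 24 genes fell and none rose, also adjusted over the list alone (camera adjusted p = 2.26e-06, 0.0203 with an estimated correlation). Its metallothionein MT1G fell by 2.08 ± 0.24, a call that was lost when probe sets shared between transcripts were left out and another probe set stood for the gene (-1.08, adjusted p = 0.297).

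Inflammatory and stromal lists were higher in CD38-low cells under camera's preset correlation, but not with an estimated one. Of 29 NF-kB and cytokine genes 7 rose and none fell (12 rises adjusted over the list alone; camera adjusted p = 1.28e-06, 0.111 with an estimated correlation). The neutrophil-attracting chemokine CXCL6 rose by 3.24 ± 0.35. MHC class II presentation had 2 rises out of 9 (4 adjusted over the list alone; camera adjusted p = 0.000632, 0.141 with an estimated correlation). HLA-DMA rose by 1.74 ± 0.38. Of 20 immediate-early and dissociation stress genes 5 rose (6 adjusted over the list alone; camera adjusted p = 0.000386, 0.280 with an estimated correlation). NR4A2 rose by 1.75 ± 0.28 and the heat shock co-chaperone DNAJB1 by 1.20 ± 0.27. TGF-beta and mesenchymal transition had 8 rises out of 21 (9 rises and 1 fall adjusted over the list alone; camera adjusted p = 0.00100, 0.268 with an estimated correlation). The matrix protease MMP2 rose by 3.55 ± 0.78.

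Some markers of fibroblasts and smooth muscle were also higher than in CD38-positive cells. Of 5 tested fibroblast markers 2 rose (4 adjusted over the list alone; camera adjusted p = 0.00211, 0.265 with an estimated correlation), PTGDS by 4.51 ± 1.09 and the matrix protein FBLN1 by 3.88 ± 0.65. Of 8 smooth muscle markers 4 rose (5 adjusted over the list alone; camera adjusted p = 9.5e-05, 0.0674 with an estimated correlation), SYNPO2 by 3.15 ± 0.43 and the actin ACTA2 by 2.67 ± 0.48. Apart from PTGDS these genes were about as high in basal cells, with mean log2 signals in basal and CD38-low cells of 9.75 and 9.99 for FBLN1, 8.12 and 8.11 for SYNPO2, 9.05 and 9.40 for ACTA2 and 6.96 and 10.1 for PTGDS, and the smooth muscle marker TAGLN was higher in basal cells (12.1 and 9.98). The rises of FBLN1, SYNPO2 and ACTA2 thus go with the basal signal as well. The mean log2 signal of the fibroblast markers was 9.60 ± 2.15 (SD, n = 4) in the CD38-low gate, with 12.4 on replicate 2 and 7.30 on replicate 3, against 6.69 ± 0.736 in CD38-positive and 7.72 ± 0.304 in basal cells. The NF-kB list mean was also highest on CD38-low replicate 2 (12.2) and lowest in that gate on replicate 3 (11.3). With the fibroblast mean as a covariate, the mean of the TGF-beta list went from 0.99 to 0.13 (camera adjusted p = 0.806), and 9 genes named above lost their calls (limma adjusted p from 0.0539 to 0.710). Their differences were then 3.75 ± 1.32 for SPRR3, 3.85 ± 1.26 for SPRR1B, 1.56 ± 0.69 for FZD10, 1.20 ± 0.36 for NR4A2, 1.19 ± 0.40 for DNAJB1, 0.73 ± 0.45 for MMP2, 0.81 ± 0.82 for PTGDS, 1.58 ± 0.42 for FBLN1 and 1.23 ± 0.47 for ACTA2. PTGDS and FBLN1 are among the 5 markers in the fibroblast mean, so their lost calls were favoured in advance and show nothing. The covariate also widened the SE of some genes. DNAJB1 stood at 1.20 ± 0.27 without it, and SPRR3 and SPRR1B at 4.75 ± 0.93 and 4.67 ± 0.88. A lost call alone thus does not tie a gene to fibroblast signal. With the donor as a block beside the covariate, SPRR3 and SPRR1B passed (5.37 ± 0.79 and 5.37 ± 0.73, adjusted p = 0.00846 and 0.00456) and the 7 others did not. Of these, FZD10 stood at 0.24 ± 0.68, NR4A2 at 0.35 ± 0.40, DNAJB1 at 0.64 ± 0.45, MMP2 at 0.97 ± 0.61, PTGDS at 2.08 ± 0.68, FBLN1 at 1.15 ± 0.59 and ACTA2 at 0.42 ± 0.53 (adjusted p from 0.222 to 0.964). The mean of the TGF-beta list was then -0.21 (camera adjusted p = 0.357), and 82 genes were higher and 62 lower. With the covariate and no block 265 genes were higher and 231 lower, 1520 of the 1523 genes called without it kept their sign and 444 were still called. Leaving out the 2 CD38-low arrays with the most fibroblast signal gave 505 and 384.

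**Figure D2:**
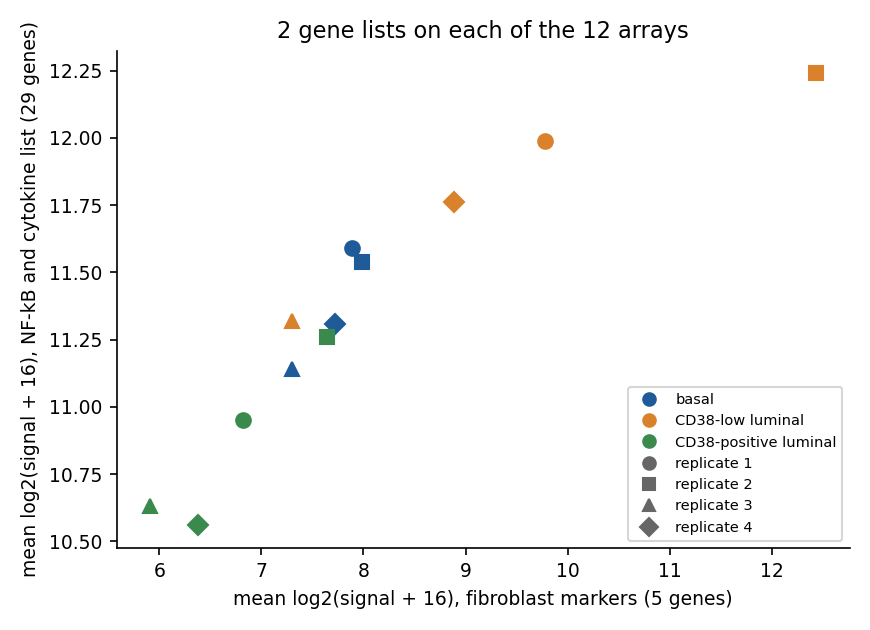
Mean log2(signal + 16) of 5 fibroblast markers (x axis) and of 29 NF-kB and cytokine genes (y axis) on each of the 12 arrays, with colour for the population and symbol for the replicate. CD38-low replicate 2 is highest on both axes (12.4 and 12.2), and the CD38-positive arrays lie between 5.91 and 7.64 on the x axis and between 10.6 and 11.3 on the y axis.

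Smaller metabolic shifts followed. Lipid and sterol synthesis had 5 falls and 2 rises out of 21 (8 falls and 2 rises adjusted over the list alone; camera adjusted p = 0.00130, 0.117 with an estimated correlation). The acyl-CoA synthetase ACSL1 fell by 1.02 ± 0.25 and the nuclear receptor PPARG rose by 1.11 ± 0.24. ACSL1 lost its call with the fibroblast covariate (-0.57 ± 0.33, adjusted p = 0.431), as did the lipid list (-0.24, adjusted p = 0.0553), which passed with the donor as a block beside it (-0.52, adjusted p = 0.000127). NAD metabolism had 3 falls out of 17, also adjusted over the list alone, of which NAMPT, the main enzyme of NAD salvage, fell by 0.94 ± 0.19 (camera adjusted p for the list = 0.0370, 0.117 with an estimated correlation). This list's call was lost without CD38-low replicate 4 (adjusted p = 0.0576) and without CD38-positive replicate 1 (0.0628). The camera tests of the sort marker list (0.226), complement and acute phase (0.211), interferon response (0.468), cell cycle (0.211), endoplasmic reticulum and unfolded protein genes (0.633), Notch (0.226), oxidative phosphorylation (0.670), glutathione and oxidant defence (0.793), endothelium (0.226) and urothelium (0.402) did not pass. For the interferon, endoplasmic reticulum, oxidative phosphorylation and glutathione lists the mean was above 0 while camera's direction was down, and the interferon median (-0.03) was below 0. Leukocytes, neuroendocrine cells, seminal vesicle, erythrocytes and Schwann cells had at most 2 markers past the filter and no test, and their median log2 differences over all markers on the array were 0.178, 0.172, -0.932, -0.0681 and -0.223.

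Over all 12097 genes tested, 906 were higher and 617 lower in CD38-low than in CD38-positive luminal cells (limma, Benjamini-Hochberg adjusted p under 0.05), and 1512 of the 1523 had the same sign in all 4 donors. The lower count was 401 without CD38-positive replicate 2 and 958 without basal replicate 4, which enters the shared estimate of the spread.

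The comparison of CD38-low luminal with basal cells asks what sets the same gate apart from the basal layer. CD38-low cells rose most in ceruloplasmin CP (4.29 ± 0.70), the gel-forming mucin MUC5AC (4.07 ± 0.63), the anion transporter SLC26A4 (4.02 ± 0.51), the secretoglobin SCGB3A1 (3.91 ± 0.44), the protease inhibitor SERPINA3 (3.83 ± 0.64) and the phospholipase PLA2G2A (3.69 ± 0.54). PIGR, which carries antibodies across epithelia, rose by 3.79 ± 0.94 and BPIFB1 by 3.71 ± 0.89. Their calls were lost without basal replicate 2 (3.42 and 3.20, adjusted p = 0.0629 and 0.0557) and without CD38-low replicate 1 (3.63 and 2.99, 0.0549 and 0.0555). Leaving out 1 open reading frame placeholder, the largest falls were those of the calcium sensor VSNL1 (-3.53 ± 0.34), the small GTPase RAB38 (-3.34 ± 0.54), the receptor NOTCH4 (-3.30 ± 0.40), the transcription factor BNC1 (-3.26 ± 0.44), the basement membrane collagen COL4A6 (-3.02 ± 0.39), the cytokine IL1B (-2.97 ± 0.38), the transcription factor FOXE1 (-2.92 ± 0.34) and the receptor FGFR3 (-2.89 ± 0.24). Adjusted p-values of these 16 genes ranged from 2.06e-05 to 0.0184. ITGA6 fell by 1.73 ± 0.21, EPCAM did not pass (0.20 ± 0.16), and CD38 rose by 1.27 ± 0.34 (limma adjusted p = 0.0295), a call that was lost without basal replicate 1 or 2 (1.25 and 0.96, adjusted p = 0.0523 and 0.0795) and without CD38-low replicate 1, 3 or 4 (1.21, 1.31 and 1.08, adjusted p = 0.0768, 0.0540 and 0.0853).

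Basal genes fell as a group, with 17 falls, no rise and 5 members that did not pass out of 22 (19 falls adjusted over the list alone; camera adjusted p = 1.64e-14, 0.00109 with an estimated correlation). KRT5 fell by 2.51 ± 0.28 and NOTCH4 was the largest fall. Secretory luminal genes had 14 rises and 1 fall out of 23 (16 rises and 1 fall adjusted over the list alone; camera adjusted p = 8.89e-12, 0.0454 with an estimated correlation). The acid phosphatase ACP3 rose by 3.50 ± 0.44. Androgen-responsive genes had 6 rises and 1 fall out of 29 (6 and 2 adjusted over the list alone; camera adjusted p = 0.0449, 0.437 with an estimated correlation). The kallikreins KLK3 and KLK2 rose by 3.43 ± 0.29 and 3.24 ± 0.41. That list's call was also lost with the donor as a block (adjusted p = 0.0662) and without basal replicate 1 or 2, CD38-low replicate 3 or 4, or CD38-positive replicate 3 (adjusted p = 0.0886, 0.129, 0.0567, 0.0635 and 0.0530).

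Club and hillock genes had 9 rises and 1 fall out of 28 (11 and 2 adjusted over the list alone; camera adjusted p = 0.00163, 0.406 with an estimated correlation). CP and SCGB3A1 were its largest rises. Complement and acute phase had 4 rises out of 12 (7 rises and 1 fall adjusted over the list alone; camera adjusted p = 0.00323, 0.406 with an estimated correlation). Complement factor B, CFB, rose by 2.79 ± 0.46 and did not pass when shared probe sets were left out and another probe set stood for it (2.06, adjusted p = 0.0518). MHC class II presentation had 2 rises out of 9 (3 adjusted over the list alone; camera adjusted p = 0.00163, 0.406 with an estimated correlation). Of 29 NF-kB and cytokine genes 6 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0220, 0.528 with an estimated correlation). The chemokine CXCL3 rose by 2.00 ± 0.39 while IL1B fell. The NF-kB call was lost without CD38-low replicate 2, the array with the most fibroblast signal (mean 0.30, adjusted p = 0.0667), and with the fibroblast covariate (mean 0.05, adjusted p = 0.480). Oxidative phosphorylation had 4 falls out of 28, also adjusted over the list alone (camera adjusted p = 0.00218, 0.437 with an estimated correlation). The cytochrome CYC1 fell (-0.98 ± 0.22). Camera also gave adjusted p = 0.0195 for interferon response (5 rises out of 27, of which 1 was higher in 3 of the 4 donors only, and 6 adjusted over the list alone), 0.0111 for immediate-early genes (1 rise out of 20, 4 adjusted over the list alone), 0.0423 for urothelium (2 rises out of 6, also adjusted over the list alone, UPK1A by 2.12 ± 0.45) and 0.0437 for fibroblasts (no member out of 5 passing, 2 rises adjusted over the list alone).

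With an estimated correlation these last 4 lists had adjusted p = 0.528, 0.528, 0.406 and 0.528. Their calls were lost when single arrays were left out, for interferon response without basal replicate 2 or 4 or CD38-low replicate 1 (adjusted p = 0.131, 0.0687 and 0.0965). For immediate-early genes this was so without basal replicate 1 (0.0760), for urothelium without basal replicate 1 or 2 or CD38-low replicate 1 or 3 (0.0760, 0.131, 0.0657 and 0.127), and for fibroblasts without any basal array, CD38-low replicate 1 or 2 or CD38-positive replicate 3 (adjusted p from 0.0512 to 0.390). The fibroblast markers DCN (3.12 ± 1.01, adjusted p = 0.0586) and PTGDS (3.18 ± 1.09, 0.0727) were higher in all 4 donors without passing, and they passed in the paired fit with the donor as a block (adjusted p = 0.00975 and 0.00216) and without CD38-low replicate 3 (4.22 and 4.40, adjusted p = 0.00733 and 0.0156). PROM1 rose by 2.60 ± 0.40 and LY6D, a marker of basal and progenitor cells, fell by 2.43 ± 0.38, and the progenitor list did not pass (camera adjusted p = 0.901), with its median below 0 and its mean above. In the Notch list the ligand JAG2 fell by 2.31 ± 0.26, and in the Wnt list AXIN2, a feedback inhibitor, rose by 1.90 ± 0.34 and the ligand WNT7A fell by 1.72 ± 0.32 (camera adjusted p = 0.764 and 0.181). Lysozyme LYZ rose by 2.53 ± 0.39. The median and the mean also differed in sign for the Notch (0.20 and -0.20) and cell cycle (0.01 and -0.03) lists, and for the glutathione and polyamine lists camera's direction was down with both above 0. TGF-beta genes did not pass (camera adjusted p = 0.144) and passed without CD38-low replicate 3 (0.0197). For the sort markers the median (0.20) was above 0 and the mean (-0.09) below. No other list passed. Without the 2 CD38-low arrays with the most fibroblast signal, the calls of PIGR, CD38, CXCL3 and AXIN2 were lost (3.85, 1.48, 1.54 and 1.52, adjusted p = 0.0884, 0.0597, 0.0718 and 0.0539).

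In all, 701 genes were higher and 773 lower in CD38-low luminal than in basal cells (limma, Benjamini-Hochberg adjusted p under 0.05), so that 47.6% of the calls were higher. With each array centred on its median the share was 31.3%, with 1163 genes lower, and the median difference of all genes moved from 0.003 to -0.10. Without basal replicate 2 the counts were 397 and 373, without CD38-low replicate 1 they were 393 and 418, and without CD38-low replicate 4 they were 453 and 475, while 448 genes were lower without CD38-low replicate 3. With the fibroblast covariate 462 genes were higher, and 246 were higher and 203 lower with the donor as a block beside it, and without the 2 CD38-low arrays with the most fibroblast signal the counts were 294 and 321.

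The comparison of CD38-positive luminal with basal cells gives the distance between the gate labelled mature luminal and the basal gate. DPP4 rose by 7.12 ± 0.50, ACP3 by 6.54 ± 0.44, NPY by 6.47 ± 0.31, CD177 by 6.36 ± 0.31, CWH43 by 6.14 ± 0.50 and KLK2 by 5.79 ± 0.41. FOLH1, the prostate-specific membrane antigen, rose by 6.01 ± 0.56, and the probe set of its near-identical copy FOLH1B by 6.40 ± 0.40, which cannot be assigned to either gene with certainty. The largest falls were those of VSNL1 (-6.79 ± 0.34), KRT13 (-6.43 ± 0.50), CLCA4 (-6.21 ± 0.36), KRT5 (-6.17 ± 0.28), CAV1 (-5.91 ± 0.39), the antimicrobial ribonuclease RNASE7 (-5.72 ± 0.40) and the growth factor binding protein IGFBP3 (-5.40 ± 0.37). The probe set of MIR205, which reads the host transcript and not the mature microRNA, fell by 5.88 ± 0.35. Adjusted p-values of these 16 genes ranged from 1.57e-08 to 2.84e-06. CD38 rose by 4.70 ± 0.34, ITGA6 fell by 2.10 ± 0.21 and EPCAM did not pass (0.23 ± 0.16). Without the 2 arrays that stand apart, basal replicate 4 and CD38-low replicate 2, EPCAM was higher than in basal cells in CD38-positive (0.36, limma adjusted p = 0.0263) and in CD38-low cells (0.44, 0.0281).

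Secretory luminal genes had 19 rises, no fall and 4 members that did not pass out of 23 (20 rises and 1 fall adjusted over the list alone; camera adjusted p = 4.05e-17, 0.0127 with an estimated correlation). Basal genes had 19 falls and 1 rise out of 22, also adjusted over the list alone (camera adjusted p = 1.06e-11, 0.00279 with an estimated correlation), and MME, the member that rose, did so by 1.77 ± 0.28. The Wnt list had 11 falls and 1 rise out of 17, also adjusted over the list alone (camera adjusted p = 0.000528, 0.0190 with an estimated correlation). DKK3 fell by 4.58 ± 0.33 and the secreted Wnt inhibitor WIF1 fell by 4.24 ± 0.51, while AXIN2 rose by 1.50 ± 0.34. Androgen-responsive genes had 15 rises and 5 falls out of 29 (17 and 5 adjusted over the list alone; camera adjusted p = 0.000132, 0.110 with an estimated correlation). KLK3 rose by 5.10 ± 0.29 and HPGD fell (-2.30 ± 0.38). The polyamine, citrate and zinc list had 8 rises and 3 falls out of 24 (11 and 4 adjusted over the list alone; camera adjusted p = 0.00635, 0.129 with an estimated correlation). The isocitrate dehydrogenase IDH2 rose by 3.35 ± 0.45 and MT1G by 2.57 ± 0.24.

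Further lists passed with the preset correlation and not with an estimated one. Lipid and sterol synthesis had 8 rises and 2 falls out of 21, also adjusted over the list alone (camera adjusted p = 0.0190, 0.293 with an estimated correlation). ACSL1 rose by 1.80 ± 0.25 and the sterol sensor partner INSIG1 by 1.44 ± 0.22. The lipid list's call was lost without basal replicate 2 (adjusted p = 0.0516). Club and hillock genes had 13 falls and 2 rises out of 28 (13 and 3 adjusted over the list alone; camera adjusted p = 0.0214, 0.518 with an estimated correlation). SCGB1A1 fell (-4.80 ± 0.46). The club list's call was lost without basal replicate 1 (adjusted p = 0.0970). Interferon response had 10 rises, of which 1 was seen in 3 of the 4 donors only, and 4 falls out of 27 (10 and 5 adjusted over the list alone; camera adjusted p = 0.0363, 0.614 with an estimated correlation). CXCL11 rose by 2.51 ± 0.32 and IFIT2 by 2.02 ± 0.37. The interferon list's call was lost without basal replicate 2 or 4 or CD38-positive replicate 1 (adjusted p = 0.120, 0.0825 and 0.0564). Progenitor-associated genes had 6 falls and 1 rise out of 15, also adjusted over the list alone (camera adjusted p = 0.0419, 0.129 with an estimated correlation). LY6D fell (-4.88 ± 0.38), as did the receptor KIT (-2.37 ± 0.57). The progenitor list's call was lost without basal replicate 2, 3 or 4 or CD38-positive replicate 1 or 2 (adjusted p = 0.0949, 0.0877, 0.0830, 0.0564 and 0.0632). Smooth muscle markers had 5 falls out of 8, also adjusted over the list alone (camera adjusted p = 0.0325, 0.321 with an estimated correlation). TAGLN fell (-3.91 ± 0.31), as did SYNPO2 (-3.16 ± 0.43). The smooth muscle list's call was lost without CD38-positive replicate 1 (adjusted p = 0.0508). With the donor as a block the interferon, progenitor and smooth muscle lists each had adjusted p = 0.0572. The NF-kB list did not pass (camera adjusted p = 0.0996). IL1B fell (-3.87 ± 0.38) and IL1A (-3.38 ± 0.54) while the adhesion molecule ICAM1 rose by 1.29 ± 0.23. The NF-kB list passed without CD38-positive replicate 2 (adjusted p = 0.0315). Oxidative phosphorylation had adjusted p = 0.0525, and passed without basal replicate 3 or 4 or CD38-positive replicate 3 (0.0348, 0.00646 and 0.0169). For MHC class II the median was above 0 and the mean below (0.02 and -0.14), as for glutathione and oxidant defence, and no other list passed.

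In this comparison 1612 genes were higher and 1994 lower (limma, Benjamini-Hochberg adjusted p under 0.05), more than in either comparison of the CD38-low gate. Without basal replicate 4, which stood apart on PC2, the counts were 1893 and 2294.

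**Figure D3:**
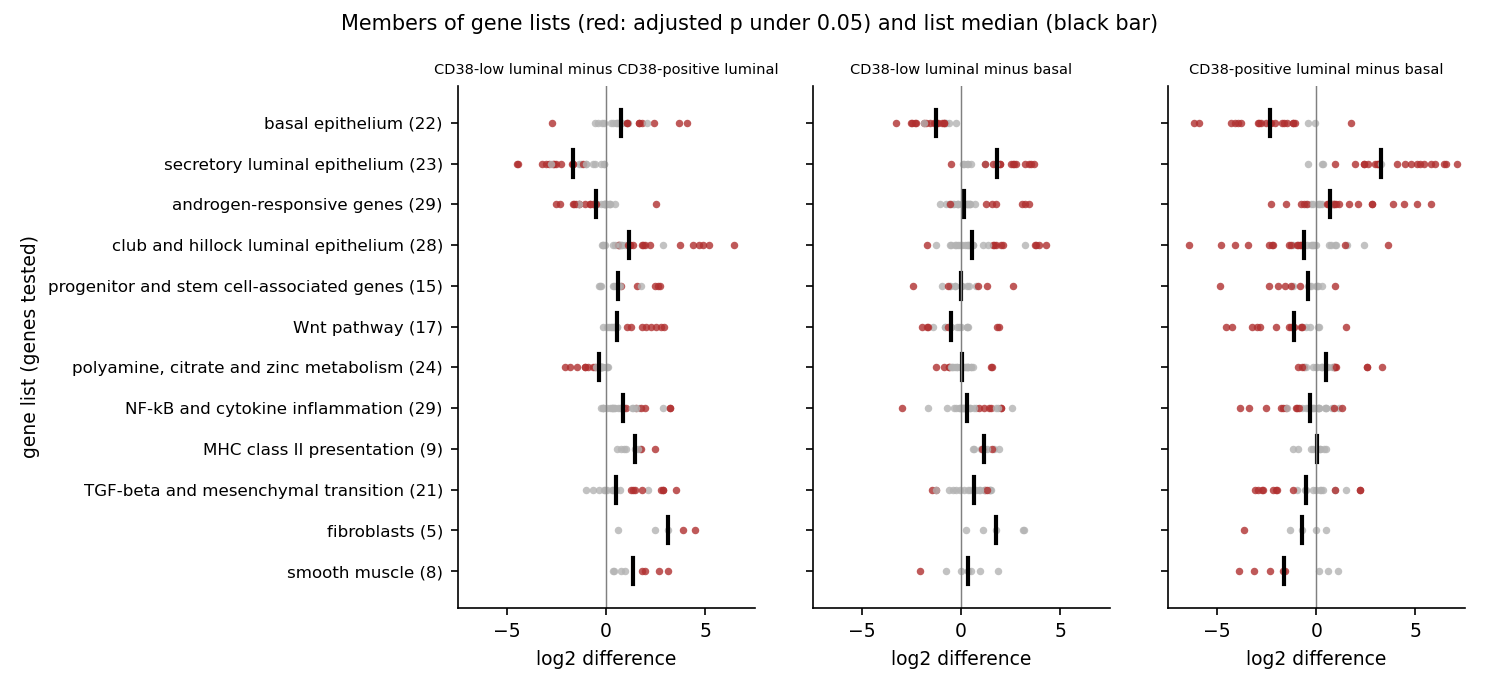
Log2 differences of the tested members of 12 gene lists in the 3 comparisons, 1 point per gene, red where the adjusted p is under 0.05, with the list median as a black bar and the number of genes tested in parentheses. The basal list median is 0.76 for CD38-low minus CD38-positive luminal cells, -1.27 for CD38-low minus basal and -2.31 for CD38-positive minus basal, and the secretory list medians are -1.67, 1.82 and 3.27.

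The place of the CD38-low gate between both other populations was measured in each donor over genes picked in the 3 other donors. Over the genes higher in CD38-positive luminal than in basal cells (745 to 1110 genes), the CD38-low arrays lay at 0.473 ± 0.0945 (SD, n = 4 donors; 0 is basal and 1 is CD38-positive luminal), ranging from 0.357 to 0.577. Over the genes lower in CD38-positive luminal cells (815 to 1115 genes) they lay at 0.343 ± 0.121, ranging from 0.221 to 0.498. KLK2 and ACP3 had intermediate levels in CD38-low cells (10.6 ± 0.548 and 11.3 ± 0.858, SD), as did KRT5 (11.5 ± 0.620), whereas SCGB3A1 (13.0 ± 0.0907) and PROM1 (9.51 ± 0.759) were above both other populations. The plot of 12 genes by population shows these levels on each array.

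**Figure D4:**
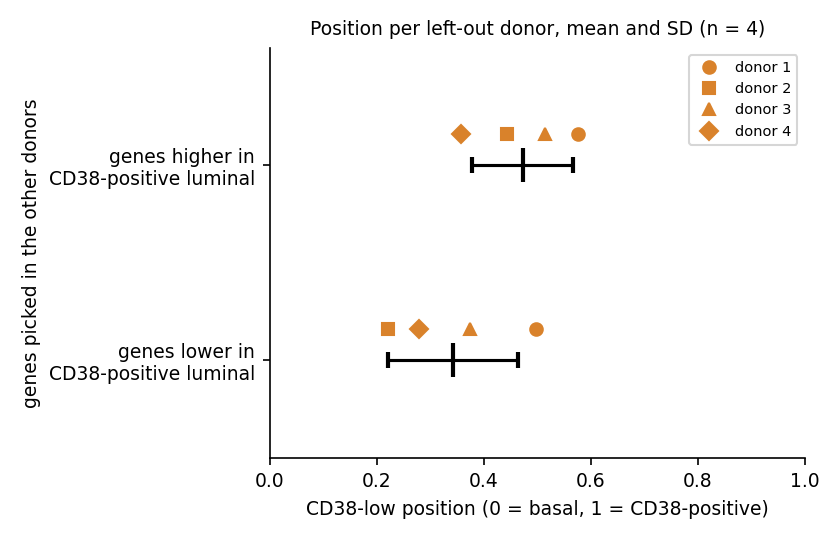
Position of the CD38-low gate per left-out donor (points, symbol for donor) with mean and SD (n = 4, black), on a scale from 0 for basal to 1 for CD38-positive luminal cells. All 8 positions lie between 0.221 and 0.577.

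**Figure D5:**
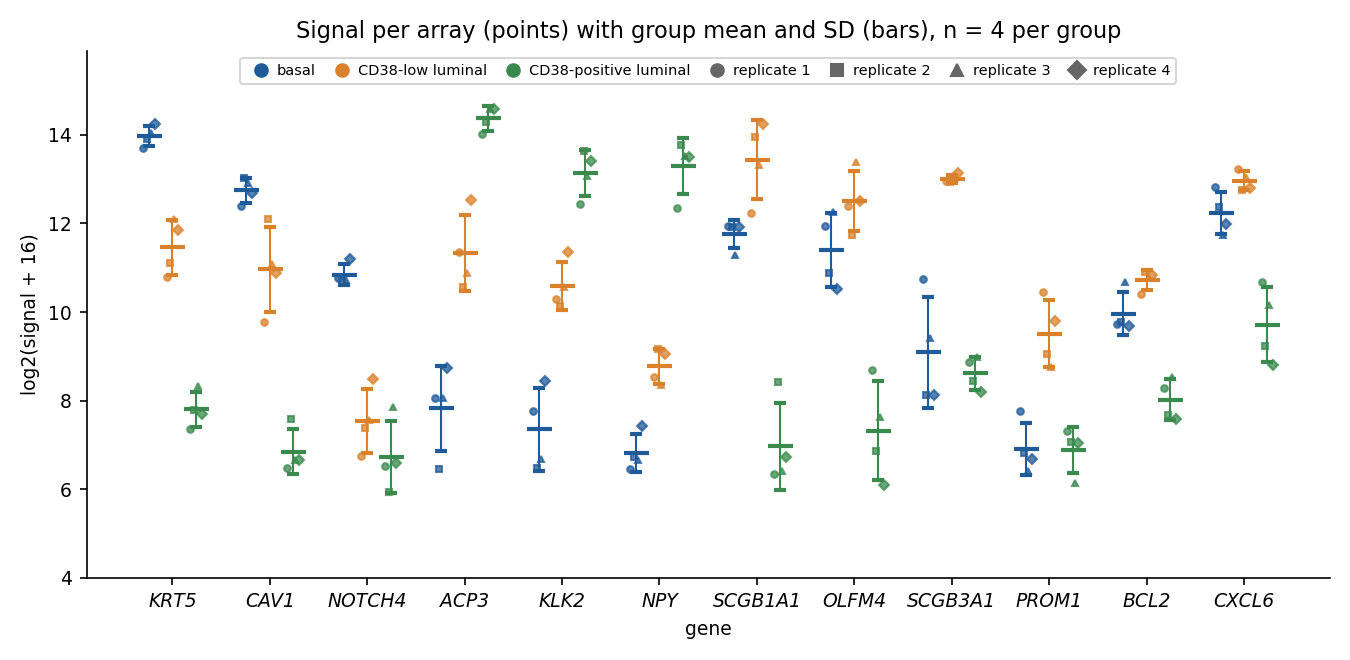
Log2(signal + 16) of 12 genes named in the text on each array (points, symbol for replicate), with group mean and SD (bars, n = 4), for basal, CD38-low luminal and CD38-positive luminal cells. KRT5 has group means of 14.0, 11.5 and 7.80, and ACP3 of 7.83, 11.3 and 14.4, in that order, while PROM1 is highest in the CD38-low gate (9.51).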

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

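The tests of fibroblast signal as an explanation and the covariates with the donor as a block were chosen after the result was seen, and the other tests before the data were examined. An array stood apart from its 3 group mates, with a gap to the nearest over the group's range above Dixon's critical value, in 23 of 362 groups of 4 tested, where chance gives about 1 in 20, or 18.1. Each set of values below is that of the array (log2 signal for genes and lists), the range of its group mates and the gap over the range.

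Basal replicate 4 stood apart 7 times. Its median signal (168 against 86.8 to 88.6, 0.978) and its percent of probe sets over 100 (64.6 against 47.7 to 48.1, 0.978) were highest in the group, and its mean correlation with the group (0.871 against 0.930 to 0.936, 0.905) was lowest. On it NOTCH4 (11.2 against 10.7 to 10.8, 0.867) and FOLH1 (6.70 against 4.06 to 4.38, 0.878) were highest, and IDH2 (7.17 against 9.31 to 9.73, 0.838) and the endoplasmic reticulum list (11.2 against 11.7 to 11.8, 0.840) lowest. Basal replicate 1 was highest for CWH43 (6.16 against 4.09 to 4.15, 0.973) and lowest for DRAIC (4.18 against 4.74 to 4.79, 0.928). Basal replicate 3 was lowest for SCGB1A1 (11.3 against 11.9 to 11.9, 0.962) and highest for BCL2 (10.7 against 9.68 to 9.77, 0.903), and basal replicate 2 was lowest for the urothelium list (5.83 against 6.75 to 6.86, 0.895).

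In the CD38-low gate, replicate 1 was lowest for the basal list (9.79 against 10.1 to 10.1, 0.938), replicate 2 lowest for HLA-DMA (8.34 against 9.64 to 9.86, 0.852) and highest for RAB38 (6.73 against 4.30 to 4.51, 0.913), and replicate 4 lowest for CNTNAP2 (4.22 against 5.90 to 6.12, 0.882). Among CD38-positive arrays, replicate 1 was highest for the interferon list (9.70 against 9.27 to 9.33, 0.850). Replicate 2 was highest for ITGA6 (12.2 against 11.3 to 11.4, 0.883) and CAV1 (7.59 against 6.48 to 6.67, 0.829) and lowest for ACTA2 (6.26 against 6.86 to 6.90, 0.942). Replicate 3 was lowest for IL1B (4.96 against 5.95 to 6.10, 0.866) and LY6D (6.90 against 7.71 to 7.87, 0.842), and replicate 4 was lowest for the urothelium list (6.53 against 7.32 to 7.43, 0.879).

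For each count of changed genes, only 1 of the 35 splits of its pair of groups, the real one, gave as many. This met the bound set in advance. The real splits gave 1523, 1474 and 3606 genes and the highest others 1, 45 and 2 for CD38-low with CD38-positive luminal, CD38-low luminal with basal and CD38-positive luminal with basal cells. Among the 8 splits that part all donors the highest other was 0 in each. Splits other than the real one mix both populations within a group, which widens its spread. Their low counts were thus favoured in advance and do not exclude chance, and 8 splits are few.

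Basal-list genes were higher in CD38-low than in CD38-positive luminal cells, which might reflect basal cells carried over by the sort or a basal program in the gate. Carried-over cells bring their transcripts in like shares, and over 13 strongly basal genes the median share was 12.3%, 23.8%, 26.2% and 26.6% in the 4 donors. The upper over the lower quartile of the shares was 2.99, 3.59, 3.94 and 1.98. The bound set in advance for excluding carry-over had to be passed in all 4 donors. Both 2.99 and 1.98 fell short of it, so the explanations cannot be told apart. Shares of single genes spread widely over the group means, from 4.91% for NOTCH4 and 13.3% for KRT14 to 44.6% for TRIM29.

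In CD38-low cells 81 genes lay above both other populations. A mixture of basal and CD38-positive cells alone is argued against, since 100 simulated mixtures gave at most 4 such genes. With the fibroblast covariate the median of the smaller difference was 0.998 of its value without it (1.32 in both). All 81 differences stayed above 0 and 23 genes were still called. With the donor as a block beside it the share was 1.02, 80 differences stayed above 0 and 12 genes were still called. Both shares are past the bound for excluding carried-over fibroblasts as the whole source. The 81 genes were picked on these same arrays, though, by a test that favours genes with little spread within a group. Fibroblast signal varied widely within the CD38-low gate, so the shares were partly set by the picking and do not exclude fibroblasts. As a hypothesis found and tested on the same data, these genes may mark a state of the sorted CD38-low cells.

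NF-kB and cytokine genes were higher in CD38-low than in CD38-positive luminal cells (list mean difference 0.98 ± 0.22, SE, 12 arrays; 7 of 29 members passing). Camera passed this list with the preset correlation and not with an estimated one (adjusted p = 1.28e-06 and 0.111). With the donor as a block the difference was 0.98 ± 0.10. Dissociation stress that the immediate-early mean does not read cannot be judged here. As far as that mean reads it, stress as the whole source is argued against by the fits on all 12 arrays. The difference was 1.17 ± 0.34 with the immediate-early mean as covariate and 0.60 ± 0.17 with the donor as a block beside it (shares of 1.20 and 0.614). Without CD38-low replicate 2 the fit with the donor as a block left 0.50 ± 0.20 (a share of 0.537), over 2 SE. That fit had few arrays for its number of terms, so 2 SE is a loose bound there and decides little. With the fibroblast mean as a further covariate, the fit without that replicate left 0.41 ± 0.23, within 2 SE of 0. On all 12 arrays both covariates left 0.61 ± 0.17 without the donor and 0.60 ± 0.19 with the donor as a block, each over 2 SE. These fits disagree, so stress and fibroblasts together stay open. Leukocytes, which the CD45 gate should remove, stay open. LAPTM5 (93.6 in CD38-low and 38.1 in CD38-positive cells), FCER1G (97.8 and 56.8), ITGB2 (64.8 and 41.7) and LYZ (735 and 440) had higher mean signals in CD38-low cells, and PTPRC (10.4 and 15.6), TYROBP (74.7 and 89.3) and CORO1A (45.8 and 49.8) lower. LYZ and CORO1A, the markers past the filter, were each higher in 2 donors and lower in 2 (limma adjusted p = 0.298 and 0.951). The median log2 difference of all 22 leukocyte markers (0.178) was under the bound set in advance for excluding leukocytes, but it decides nothing, since 13 were higher and 9 lower and 20 did not pass the filter. Fibroblasts stay open, since the fits with their mean as covariate disagree. The covariate left 0.38 ± 0.17 without the donor (0.381 on the list mean, a share of 0.388), and 0.68 ± 0.17 with the donor as a block (a share of 0.697), which is past the bound for excluding them as the whole source. That fit leant on CD38-low replicate 2, without which 0.44 ± 0.21 was left, a share of 0.475 and under that bound. The EpCAM gate should remove fibroblasts, yet mean signals in CD38-low cells were 3343 ± 5224 for PTGDS, 2464 ± 3740 for DCN, 1436 ± 1552 for COL1A1 and 860 ± 1305 for LUM (SD, n = 4). Replicate 2 carried most of this, and without it the means were 744, 613, 675 and 214. The means of these genes were 74.3, 88.6, 652 and 26.8 in CD38-positive cells and 133, 91.5, 454 and 14.3 in basal cells. Without replicate 2, COL1A1 was thus close to its level in CD38-positive cells. A difference between the sorted populations themselves likewise stays open.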

How the results depend on the processing

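The settings that left out the 2 CD38-low arrays with most fibroblast signal, left out 2 arrays that stand apart, or took the fibroblast covariate were chosen after seeing the data, and the others before. Of 7032 recomputed values of 260 results for named genes, 6486 kept their direction and side of the threshold, 509 no longer passed, 33 passed anew and 4 reversed. Of 2082 values of 75 list results, 1963 kept both, 103 no longer passed, 16 passed anew and 0 reversed. ACSL4 in CD38-positive luminal minus basal cells reversed to 0.0236 without shared probe sets. GSTA1 reversed to -0.31 (CD38-low minus CD38-positive) and -0.19 (CD38-low minus basal) without the 2 CD38-low arrays with most fibroblast signal, and to -0.19 (CD38-low minus CD38-positive) without the 2 arrays that stand apart. By construction, each of these values came from another probe set of the gene. Dim genes were limited by signal over background. Camera takes no block, so lists were not run with the random block, and the fibroblast list was not run with its own mean as covariate.

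At least 2-fold changes, fewer by construction, numbered 387 lower in CD38-low than CD38-positive luminal cells, 319 lower in CD38-low than basal, and 1022 higher and 1095 lower in CD38-positive than basal cells. For the other counts that moved by over 1.5 times the cause was not tested. Median centring gave 1163 genes lower in CD38-low than basal cells and 67 below both others. No filter gave 23 below both. The stricter filter, with fewer genes tested, gave 528 higher in CD38-low than CD38-positive cells and 51 above both. Without shared probe sets 465 were lower in CD38-low than basal cells and 24 below both. Only the 8 arrays compared gave 456 higher in CD38-low than basal cells and 25 below both. Array weights gave 948 lower than in CD38-positive, 1242 higher and 1433 lower than in basal cells, 162 above and 97 below both. Without the 2 CD38-low arrays with most fibroblast signal there were 505 higher and 384 lower than in CD38-positive, 294 higher and 321 lower than in basal cells, 27 above and 16 below both. Without the 2 arrays that stand apart 85 lay below both. The fibroblast covariate gave 265 higher and 231 lower than in CD38-positive, 462 higher than in basal cells and 28 above both. The RNA quality difference of CD38-low minus basal cells was -0.338 on GAPDH alone (exact permutation p = 0.0286). Positions stayed between 0.430 and 0.499 and between 0.332 and 0.394 over 9 other settings.

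In the paired fit with the donor as a block, counts above and below both were 159 and 63, and 124 and 76 with the donor as a random block (consensus correlation 0.160). Of the 1523, 1474 and 3606 calls, 1515, 1466 and 3594 stayed with the fixed block. It ended the list calls of androgen-responsive genes in CD38-low minus basal cells and of interferon, progenitor and smooth muscle genes in CD38-positive minus basal cells, and among the genes named in the text it changed the calls of DCN and PTGDS (CD38-low minus basal, now passing) and no other.

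Leaving out each array in turn gave 654 to 1221 higher and 401 to 958 lower in CD38-low than CD38-positive, 393 to 898 higher and 373 to 1079 lower in CD38-low than basal, 1292 to 1893 higher and 1579 to 2294 lower in CD38-positive than basal cells, 35 to 115 above and 15 to 74 below both, positions of 0.436 to 0.529 and 0.289 to 0.393, and RNA quality differences of -0.118 to -0.0600, -0.133 to -0.0619 and -0.0422 to 0.0254.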

Other observations

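The genes of this part were chosen after their values were seen, and the fibroblast covariate, its fit with the donor as a block, the splits and simulated groups with that block and the settings that leave out 2 arrays were chosen after seeing the data. Some of the genes above both other populations in CD38-low cells follow, given as the difference from CD38-positive luminal cells and then from basal cells. The secretoglobin SCGB3A1 was higher by 4.39 ± 0.44 and 3.91 ± 0.44, PROM1 by 2.63 ± 0.40 and 2.60 ± 0.40, the protein-folding protein ERP27 by 2.66 ± 0.52 and 2.52 ± 0.52 and AGR3, a protein disulfide isomerase relative, by 2.74 ± 0.41 and 2.45 ± 0.41 (limma adjusted p from 2.74e-05 to 0.00728), each in 4 of 4 donors. The matrix protein MGP was higher by 2.90 ± 0.68 and 3.35 ± 0.68, and its call against CD38-positive cells was lost with the fibroblast covariate (3.02 ± 1.01, adjusted p = 0.126). The glutathione transferase GSTA1 was higher by 3.04 ± 0.51 and 3.35 ± 0.51, but its probe set may also read near-identical family members, and the gene reversed to -0.31 and -0.19 where another probe set stood for it. Below both lay the galactosidase relative GLB1L2 (-2.03 ± 0.40 and -1.78 ± 0.40), the transcription factor HES2 (-1.59 ± 0.30 and -1.53 ± 0.30) and CD320, a receptor for vitamin B12 uptake (-2.66 ± 0.23 and -1.24 ± 0.23), and HES2 lost its call against CD38-positive cells with the fibroblast covariate (-1.61 ± 0.44, adjusted p = 0.0608). For MGP and HES2 the SE was wider with the covariate and the difference about as large. With the donor as a block beside the covariate they were 1.41 ± 0.82 and -1.50 ± 0.67 (adjusted p = 0.620 and 0.413).

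In all, 81 genes lay above and 39 below both in the fit without the donor, and 159 and 63 with the donor as a block. Both comparisons share the CD38-low arrays. Simulated groups with no effect gave at most 0 and 1 genes in 50 runs, and independent lists of the same sizes would share 52.5 and 39.4. With the CD38-low arrays split so that each comparison used other arrays, 10 to 20 genes lay above and 3 to 8 below both over 6 splits. With the donor as a block the simulated groups gave at most 0 and 0, independent lists would share 95.5 and 72.4, and the splits gave 19 to 34 above and 0 to 4 below both. The excess over either value is not a measure of a shared effect. Without the block, the number above both was 35 without basal replicate 2, 42 without CD38-low replicate 1, 39 without CD38-low replicate 4 and 53 without CD38-positive replicate 2. The number below both was 17 without basal replicate 2, 74 without basal replicate 4, 22, 18 and 15 without CD38-low replicates 1, 3 and 4, and 22 and 25 without CD38-positive replicates 2 and 4.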
